A study of Zea mays with 6 samples.

How the data were processed

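RNA was measured in whole maize (Zea mays) kernels 15 days after pollination, in 3 wild-type (WT) samples and 3 samples of the dek15 mutant. Groups and replicate numbers were taken from the sample titles. The labels' protocols state that total RNA was extracted from each biological sample and made into Illumina libraries; they do not say whether the kernels of a group came from separate ears or plants, so p-values measure the spread between these samples. Reads were processed with TopHat2 2.0.13 and Cufflinks 2.2.1 against B73 RefGen_v4, per the submitters' processing notes. The annotation, the read filters and the use of strand are not given in the sources used here.

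The deposited values are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), per the file headers, with 1 value per locus and library. Each library had 45765 rows, and 14 of them repeated a locus listed elsewhere, always at 0, which left 45751 distinct loci. All 6 libraries held the same loci in different row orders, and they were joined by locus. FPKM are not counts, so total counts and exact counting errors are unknown. An estimate of relative depth was tried on 250 loci longer than 1000 bp with mean FPKM under 0.08, by how many values lay at ratios of whole reads of up to 4, within 0.008 on the log2 scale. In the other libraries only 20 to 65 of the 250 loci lay on such ratios at the best offset near equal depth, against 5 to 7 at a typical offset. Offsets farther away did as well or nearly so (20 to 56 loci), so the relative depth of the libraries is not known. An exact 0 can be a failed estimate as well as an absent transcript.

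Loci carry coordinates and no gene names. Their starts count from 0 and were moved to count from 1. The build follows the processing notes. Among the loci of the mitochondrial and plastid sequences, 97 of 144 and 27 of 74 had the same start and end as an entry of the NCBI reference table (assembly Zm-B73-REFERENCE-NAM-5.0) after this step, against 0 and 0 without it, and these took the entry's symbol. No identifier in the table matched a locus of the files (0 of 45751), and nuclear coordinates of that assembly were not used. The files therefore do not pair nuclear loci with gene names. The 20 gene lists fixed before the data were examined, which covered zeins, starch synthesis, the cell cycle, cohesin and other functions, were not applied. Neither the zein share nor the mutated gene is reported.

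The test for each locus was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1), with values scaled as deposited and without covariates. It covered loci with a mean of at least 1 FPKM over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method, and a locus was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of loci with low values. The test was tried on simulated data for the 19312 loci of this comparison: it recovered 40 of 100 loci changed by 1 on the log2 scale and 83 of 100 changed by 2, and 6 of the 129 calls were loci left unchanged. Only 200 loci were changed there, with independent normal noise and no shift common to all loci. These rates therefore need not hold for the data, where many more loci were called.

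In place of the gene lists, 6 classes of loci were chosen after the data were seen: the mitochondrial genome, the plastid genome, unplaced contigs, loci under 200 bp, loci from 200 to under 300 bp, and the 20 loci of at least 300 bp with the highest mean over all libraries. Classes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the classes. Measures with 1 value per library were compared by exact two-sided permutation tests, for which the smallest p with 3 against 3 is 0.1. Called loci per chromosome and per window of 10 Mb were compared with all other tested loci by two-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method. Neighbouring loci are not independent, so these p-values are approximate.

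The planned rule for named genes asked for descriptive names and could not be applied in full. The 2 loci that rose most and the 2 that fell most by log2 change were taken among loci that passed the test, with all values of 1 group above all of the other and at least 5 FPKM in the higher group. A length of at least 300 bp and a value above 0 in every library were added after the data were seen. These conditions left 3813 loci that rose and 251 that fell.

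The alternatives were other pseudocounts, filters, scalings of the libraries, variance models, thresholds and window sizes, the replicate number as a block, and leaving out each library in turn. The median of ratios scaling used loci above 1 FPKM in every library. Other calculations and plots used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.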

Results

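Transcript levels were measured by RNA sequencing in kernels of WT maize and of the defective kernel mutant dek15, harvested 15 days after pollination, with 3 libraries per group. DEK15 is known as a subunit of the complex that loads cohesin onto chromosomes. The number of loci above 0 FPKM was 26366 ± 315 in WT and 29110 ± 379 in dek15 (SD, n = 3 each). Libraries of the same group correlated at Pearson's r of 0.911 to 0.966 across loci on the log2 scale, and libraries of different groups at 0.888 to 0.937. No pair of libraries had more than 1 identical value above 0. The first principal component held 47.2% of the variance and separated the groups. The second held 26% and set replicate 1 of both groups apart from the other libraries.

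The summed FPKM ranged from 1457925 to 3379877 in WT and from 3290551 to 8599578 in dek15 (exact permutation test, p = 0.2). Much of each sum came from loci under 300 bp, which took 55.7% ± 17.2 in WT and 79.5% ± 7.51 in dek15 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). FPKM of loci near or below the length of the sequenced fragments depend strongly on the effective length that was assumed, which the sources used here do not give, so these sums are uncertain. Loci of 1000 bp and over summed to 422371 ± 15834 FPKM in WT and 495209 ± 6665 in dek15 (SD, n = 3 each; exact permutation p = 0.1).

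The comparison of dek15 with WT asks which transcripts differ in level between mutant and normal kernels. Whole kernels were measured, so the values do not show in which tissue of the kernel a transcript differed. In the deposited values, many more loci were higher in dek15 than lower. Of 19312 loci tested, 4936 rose and 307 fell (limma, adjusted p under 0.05), so 94.1% of the calls were higher. The median log2 change over all tested loci was 0.33, and 80.3% of the tested loci had an estimate above 0. Among the calls, 1431 rose and 69 fell by at least 1 on the log2 scale.

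The size of the excess of higher calls depended on the scaling of the libraries. With median of ratios scaling, which put the median log2 change at 0.03, 1354 loci rose and 887 fell, and 60.4% of the calls were higher. All of these 1354 were among the 4936, and 304 of the 307 lower loci also fell. Without the 100 most abundant loci in the library sums, 1101 rose and 966 fell (53.3% higher). After quantile normalization, 985 rose and 1051 fell (48.4% higher). With each library scaled to a sum of 1000000, 136 rose and 152 fell (47.2% higher), with a median change of -0.48. Called in 1 direction under median of ratios, the sum without the 100 most abundant loci and quantile scaling alike were 892 higher loci and 813 lower loci. Relative to median of ratios scaling, these 892 had a median log2 change of 1.08 (lower quartile 0.80), and 492 of them rose by at least 1. The 813 had a median of -0.72 (lower quartile -0.95), and 170 fell by at least 1. Leaving out 1 library moved the 5243 calls in all by over 1.5 times in 4 cases: 2638 without WT replicate 2, 2565 without WT replicate 3, 2052 without dek15 replicate 2 and 2844 without dek15 replicate 3.

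**Figure D1:**
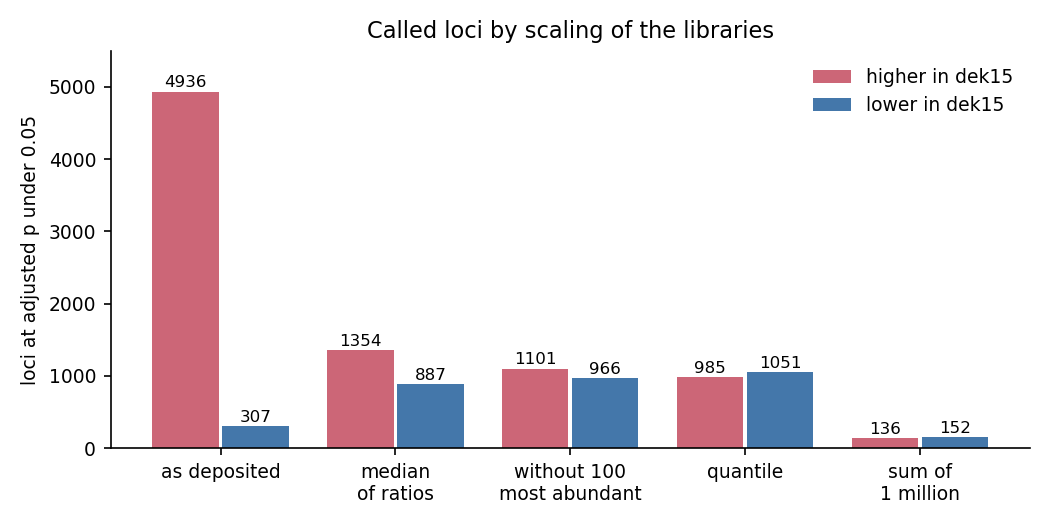
Number of loci called by limma at an adjusted p under 0.05 (vertical axis), higher or lower in dek15, for 5 scalings of the libraries (horizontal axis). As deposited, 4936 loci were higher and 307 lower, and with median of ratios scaling 1354 and 887.

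The 4 loci below had the largest changes by the naming rule, which required all libraries of 1 group to lie above all of the other. A locus of chromosome 2, from 35066062 to 35067313, was at 6.64 ± 5.17 FPKM in WT and 457 ± 241 in dek15 (SD, n = 3 each), a log2 change of 6.10 (SE 0.71; limma, adjusted p = 0.00498). A locus of chromosome 3, from 179450556 to 179452314, rose from 0.300 ± 0.249 to 27.4 ± 6.54 FPKM (log2 change 4.44, SE 0.23; adjusted p = 0.00118). A locus of chromosome 5, from 192003418 to 192004251, fell from 32.4 ± 5.02 FPKM in WT to 5.19 ± 2.08 in dek15 (log2 change -2.49, SE 0.28; adjusted p = 0.00477). A locus of chromosome 10, from 105050722 to 105054454, fell from 5.59 ± 2.55 to 0.305 ± 0.276 FPKM (log2 change -2.29, SE 0.30; adjusted p = 0.00625). Positions are in B73 RefGen_v4, and the files give neither names nor exons for these loci.

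**Figure D2:**
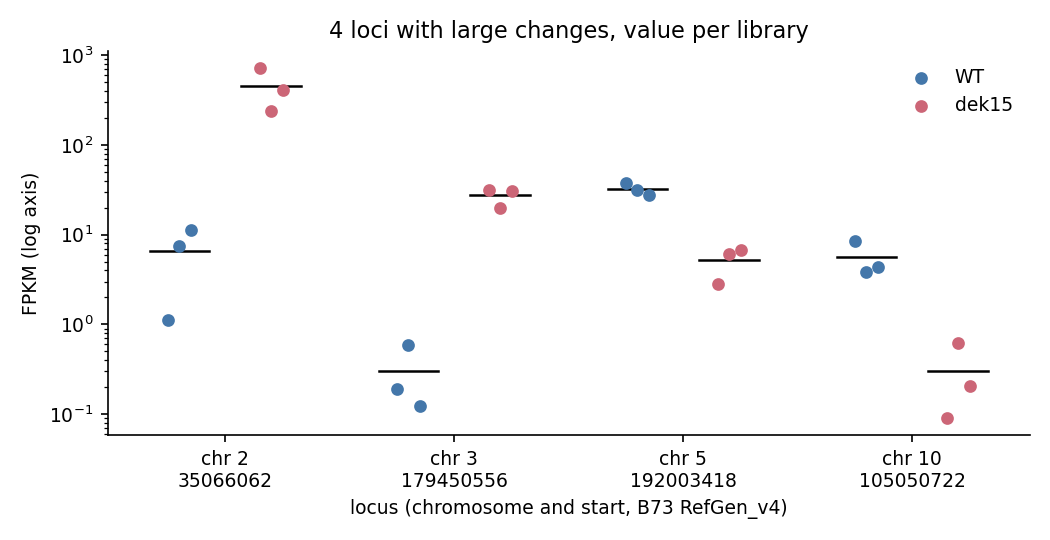
FPKM on a log axis (vertical) of the 4 loci with large changes (horizontal), with 1 point per library and a line at the mean of the 3 libraries of each group. The chromosome 2 locus lay between 1.11 and 11.3 FPKM in WT and between 241 and 717 in dek15.

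The most abundant transcripts took a smaller share of expression in dek15. The 20 most abundant loci of at least 300 bp held 47.5% ± 0.643 of the FPKM of all loci of that length in WT and 37.5% ± 4.42 in dek15 (SD, n = 3 each). Each dek15 library lay below each WT library (exact permutation p = 0.1, the smallest possible). The 20 loci summed to 435228 to 445161 FPKM in WT and to 283136, 348416 and 429048 in dek15 replicates 1 to 3. Replicate 3 of dek15 was thus close to WT in this sum. Its sum over all loci of that length was larger (1027630, against 907474 to 948033 in WT). These loci had mean values from 6174 to 69135 FPKM, 17 of them were under 1000 bp long, and 8 lay on chromosome 4 and 4 on chromosome 7. Of the 20, 2 fell and 0 rose, and 18 did not pass the test (limma); 2 also fell when adjusted over the list alone. The 2 became 0 without WT replicate 2, WT replicate 3 or dek15 replicate 2, and 1 without dek15 replicate 3. The median log2 change was -0.45 as deposited and -0.80 with median of ratios scaling. In 10 of the 20, all dek15 libraries lay below all WT libraries, and in 0 all lay above, where chance gives 5% in each direction for a single locus. The 20 loci share the same libraries, and some are neighbours or overlap, so they are not separate trials of that rate. The class was lower than other loci by camera (adjusted p = 8.1e-09), but not with an estimated correlation (adjusted p = 0.343). By fry, which tests the class against no change and not against other loci, the adjusted p was 0.0637 (0.0453 with median of ratios scaling). Of the 20, 7 lie within 5.8 to 6.4 Mb on chromosome 4, where replicates of the same group differed widely at some loci. Several of these loci lie in arrays of equal length, so reads could be split between copies and single values are uncertain.

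**Figure D3:**
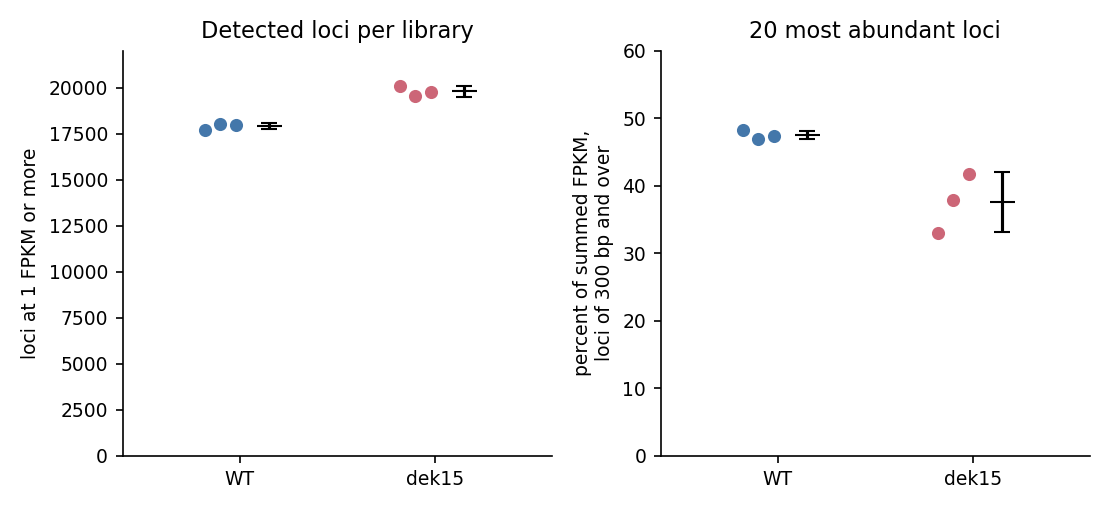
Loci at 1 FPKM or more per library (left, vertical axis) and percent of the summed FPKM of loci of at least 300 bp that the 20 most abundant loci took (right, vertical axis), by group. Points are libraries and bars are means ± SD of 3 libraries; the detected loci were 17890 in WT and 19787 in dek15 on average.

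More loci were detected in dek15. At 1 FPKM or more there were 17890 ± 166 in WT and 19787 ± 287 in dek15 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). With median of ratios scaling the numbers were 18257 ± 85 and 19330 ± 193 (SD, n = 3 each; exact permutation p = 0.1). At 10 FPKM or more the difference was 1402 loci as deposited (8114 in WT and 9516 in dek15) and 181 with median of ratios scaling (8683 and 8864). Detection also depends on sequencing depth, which is not known for these libraries, so a difference in depth is not excluded.

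Transcripts of both organelle genomes had mostly positive estimates at low levels. Of 26 mitochondrial loci tested, 24 had an estimate above 0, with a median of 0.94 against 0.33 for other loci; 2 rose, 0 fell, and 24 did not pass the test. The difference of these medians (0.611) was 0.237 without WT replicate 1 and 0.165 without dek15 replicate 3. The 2 that rose became 1 without WT replicate 1, WT replicate 3, dek15 replicate 2 or dek15 replicate 3, and 4 without dek15 replicate 1. Over all tested loci, 80.3% of estimates were above 0, and loci of the same genome are not independent. Summed over all mitochondrial loci, FPKM were 33.4, 272 and 74.3 in WT replicates 1 to 3. In dek15 they were 94.5, 252 and 558 (exact permutation p = 0.3), so the groups overlapped. The mitochondrial gene rps2A, which encodes a protein of the small ribosomal subunit, rose from 0.435 ± 0.175 FPKM in WT to 2.52 ± 0.885 in dek15 (SD, n = 3 each; log2 change 1.27, SE 0.25; limma, adjusted p = 0.0157). It did not pass after quantile normalization (adjusted p = 0.059), scaling to a sum of 1000000 (adjusted p = 0.40) or without replicate 1 of both groups (adjusted p = 0.061). It was singled out after its values were seen, as the 1 named organelle gene that passed. Ribosomal protein gene rps12 was at 73.4 ± 83.8 and 142 ± 124 FPKM, cob (apocytochrome b) at 1.24 ± 0.935 and 2.13 ± 2.19, and nad6 (a subunit of NADH dehydrogenase) at 1.04 ± 1.14 and 4.07 ± 3.62 (SD, n = 3 each), differences within the spread between replicates. All 7 plastid loci tested, among them rpl2 and rps18, had estimates above 0 (median 1.19), and 0 rose or fell by limma, with 0 of 7 adjusted over the list alone and 4 at an unadjusted p under 0.05. Their median lay 0.867 above that of other loci, and 0.496 above it without dek15 replicate 3; 2 rose without WT replicate 2. Neither class passed against other loci by camera (adjusted p = 0.894 for mitochondrial and 0.439 for plastid loci). With median of ratios scaling both did (adjusted p = 0.0274 and 0.0317), but not with an estimated correlation (adjusted p = 0.589 for both). With each library scaled to a sum of 1000000 both passed (adjusted p = 1.6e-10 and 5.8e-11), also with an estimated correlation (adjusted p = 0.0470 for both).

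Among short loci, all calls were higher in dek15 as deposited. Of 74 tested loci under 200 bp, 31 rose, 0 fell and 43 did not pass the test, with a median log2 change of 2.36 (camera, adjusted p = 0.136, and 0.950 with an estimated correlation). By camera the class was higher than other loci with median of ratios scaling (adjusted p = 7.0e-07), the sum without the 100 most abundant loci (2.0e-08), quantile normalization (7.3e-06), limma without a trend (0.0489) and without WT replicate 2 (0.00711). With an estimated correlation these gave adjusted p of 0.332 to 0.938, whereas a sum of 1000000 passed both ways (6.7e-78 and 0.00311). Of the 74, 4 rose with median of ratios scaling. The 31 became 3 without WT replicate 1, 3 without WT replicate 3, and 4, 7 and 5 without dek15 replicates 1, 2 and 3. Of 247 loci from 200 to under 300 bp, 17 rose, 0 fell and 230 did not pass. The 17 became 8 without WT replicate 2, 11 without WT replicate 3, 7 without dek15 replicate 2 and 11 without dek15 replicate 3. Leaving out any single library but dek15 replicate 2 gave 1 or 2 lower loci. The median of the class was 0.90, which lay 0.576 above that of other loci, but only 0.192 above it without dek15 replicate 3. The direction of camera, which compares mean statistics, depended on the scaling. The class was below other loci as deposited (adjusted p = 0.00394, and 0.561 with an estimated correlation), but above them without the 100 most abundant loci in the sums (0.0235), after quantile normalization (0.00641) and with a sum of 1000000 (1.8e-17, and 0.00311 with an estimated correlation). It did not pass with median of ratios scaling (0.103), without dek15 replicate 1 (0.141) or without replicate 1 of both groups (0.0675). Of 227 loci on unplaced contigs, 50 rose, 4 fell and 173 did not pass, with a median of 0.31 (17 to 25 rose without WT replicate 1, WT replicate 3 or any dek15 replicate; camera, adjusted p = 0.733, and 0.969 with an estimated correlation).

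Called loci were unevenly spread over the genome, with the highest share on chromosome 4. There 600 of 1922 tested loci were called, or 31.2% (Fisher's exact test, adjusted p = 0.000312). Chromosome 2 also had more calls than other tested loci (29.5%, adjusted p = 0.0254) and chromosome 1 fewer (24.7%, adjusted p = 0.00579). Whole chromosomes were tested only on calls as deposited, which depended on the scaling, so these differences need not hold under other scalings. The median log2 change per chromosome lay between 0.29 and 0.37 as deposited and between 0.00 and 0.08 with median of ratios scaling. Of 216 windows of 10 Mb, 4 passed. On chromosome 4, from 170 to 180 Mb, 60 of 139 loci were called (43.2%, adjusted p = 0.00525), and from 180 to 190 Mb 54 of 129 (41.9%, adjusted p = 0.0224). Fewer loci than elsewhere were called on chromosome 6 from 10 to 20 Mb (3 of 61, adjusted p = 0.00349) and on chromosome 5 from 50 to 60 Mb (10 of 87, adjusted p = 0.0332). With median of ratios scaling 2 windows passed, both with more calls: chromosome 4 from 160 to 170 Mb and from 180 to 190 Mb (adjusted p = 0.017 each).

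Over chromosome 4 from 160 to 190 Mb, a segment delimited after these windows were seen, 156 of 370 tested loci were called (42.2%, against 26.9% of all other tested loci). Within it 134 loci rose and 22 fell, and the share that fell was 5.95%, while 285 of the 18942 other loci fell. With median of ratios scaling, 42 rose and 40 fell there, in all 82 of 370 loci (11.4% elsewhere). Leaving out each library in turn gave 18.1% to 31.1% in the segment, with fewer calls elsewhere as well. The number of windows past the threshold fell from 4 to between 0 and 3 when a library was left out, with 0 without dek15 replicate 2, 1 without WT replicate 1, 1 without dek15 replicate 1 and 2 without WT replicate 2.

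**Figure D4:**
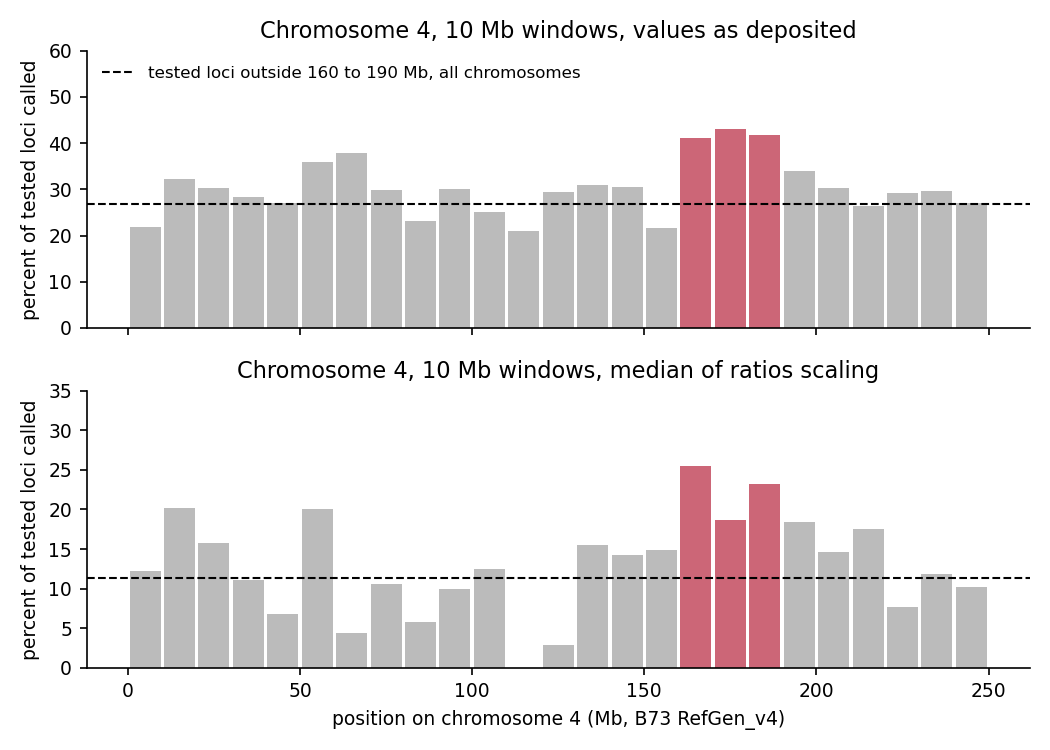
Percent of tested loci called by limma (vertical axis) in 10 Mb windows along chromosome 4 (horizontal axis, Mb), as deposited and with median of ratios scaling; the dashed line is the percent among all tested loci outside 160 to 190 Mb, which is coloured. In that segment 156 of 370 loci were called as deposited and 82 with median of ratios scaling.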

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

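The counts of calls depended on the scaling, the thresholds and the libraries used. Of 5243 called loci (4936 higher, 307 lower), the alternatives left 288 with libraries scaled to a sum of 1000000 (136 higher, 152 lower), 2241 with median of ratios scaling (1354, 887), 2067 without the 100 most abundant loci (1101, 966) and 2036 after quantile normalization (985, 1051). An adjusted p under 0.01 left 1153 (1095, 58), and a log2 change of at least 1 left 1500 (1431, 69). Leaving out 1 library gave 2052 to 3870 (1944 to 3647 higher, 103 to 282 lower). Pseudocounts, filters and variance models kept the 3 counts within 1.5 times. So did leaving out replicate 1 of both groups, which gave 4559, and keeping loci of at least 300 bp, which gave 5391, both added after the data were seen. With the replicate number as a block, 6977 loci were called (6442, 535), among them 4 of the 20 most abundant, all lower. The labels give the numbers no shared ear or day, and deviations of same-numbered libraries correlated at 0.412, 0.0360 and 0.286 across loci, so the numbers were not taken to pair the samples. Not every library correlated best with its own number, as WT replicate 2 was closest to dek15 replicate 3 (0.158). The correlations of same-numbered libraries were all positive, however, while those of different numbers ran from -0.374 to 0.158. A shared origin of same-numbered samples is therefore not excluded, and the main test leaves it out.

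Excess detected loci in dek15 (1897) kept their direction under all 9 alternatives, with 1746 to 2032 when a library was left out, and the lower share of the 20 most abundant loci (-9.95 percentage points) under all 8, with -12.0 to -7.64. The 4 nuclear loci named kept direction and side of the threshold in every fit that tested them (the chromosome 10 locus was not tested at a mean of at least 5 FPKM), with adjusted p of at most 0.0275. They were picked as extremes among called loci of the same libraries, so these fits are no independent test of them.

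Windows past the threshold numbered 4. They were 1 with 5 Mb windows, a mean of at least 5 FPKM, the sum without the 100 most abundant loci, the replicate block or without replicate 1 of both groups. They were 2 with median of ratios or quantile scaling, 0 with a sum of 1000000 or loci called under 3 other scalings, and 0 to 3 with a library left out. The 1 window of 5 Mb that passed was chromosome 6 from 10 to 15 Mb, with fewer calls (Fisher's exact test, adjusted p = 0.0166). At that size 0 windows passed on chromosome 4 from 160 to 200 Mb. Apart from the window sizes, the alternatives for the windows, the segment and the classes were chosen after the data were seen. In the segment on chromosome 4, 2.70% were called with a sum of 1000000 (1.47% elsewhere, Fisher's exact p = 0.076). Its other 19 alternatives kept more calls than elsewhere. The segment was delimited by calls from the same libraries, so these fits are no independent test of it. The 18 loci listed at 0 in WT became 44 at a floor of 0.5 FPKM, 7 at 2 FPKM, 6 at 1000 bp and over, and 23 to 37 with a library left out, where fewer libraries must meet the conditions. The shift of unplaced contigs against other loci (-0.02) changed sign to 0.020 with pseudocount 5 and 0.048 without a filter, and ran from -0.081 to 0.145 with a library left out, above 0 without WT replicate 2 and without dek15 replicate 2. The cause was not tested where none is given.

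Not run were scaling without the zein list, the zein share, the gene lists and the mutated gene, which need gene names, and count-based tests, as the values are not counts. Depth in reads is unknown, so its limits could not be set.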

Other observations

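All tests in this part were chosen after the results were seen.

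Some loci were listed at 0 in every WT library and present in every dek15 library. There were 18 such loci of at least 300 bp at 1 FPKM or more in each dek15 library, and 1 locus with the groups exchanged. The dek15 means of the 18 ran from 1.26 to 52.5 FPKM (median 2.85), and they lay on 7 chromosomes. The 6 shortest of these loci (300 to 375 bp), and 0 of the others, each had a value identical to that of another locus of the same length in at least 1 dek15 library, as values resting on few reads would have. The 18 became 29, 28 and 33 without WT replicates 1, 2 and 3, and 32 and 37 without dek15 replicates 1 and 2, where fewer libraries must meet the conditions.

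Within 5.8 to 6.4 Mb on chromosome 4, 12 loci of at least 300 bp had means of 1000 FPKM or more, and the replicates of a group differed there. Replicate 1 was the lowest library in both groups at 7 of these loci and the highest in both at 2. Deviations from the group mean correlated at 0.973, 0.848 and 0.965 across the 12 loci between libraries of the same number, and at -0.967 to 0.791 between libraries of different numbers. All 6 libraries correlated best with their own number. At 11 of the 12 loci each dek15 library lay below the WT library of the same number, and at 0 each lay above. That same-numbered samples share a haplotype there is a hypothesis. The loci were picked for this pattern, a shared harvest or day would leave the same correlations, and the 2 cannot be told apart.

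Among the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called loci as the real one, the real split itself. It called 5243 as deposited against at most 3 in any other, and 2241 against at most 2 with median of ratios scaling, where again 1 split of 10 reached the real count. A share under 0.05 is out of reach with 10 splits. Every other split mixes the groups, so any difference between them, scaling included, adds to the spread within its sides and lowers its calls. The low counts of the other splits are therefore no measure of false calls.

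That 94.1% of the calls were higher as deposited may come from fewer fragments in compact abundant loci, which leaves more for all others in a unit set relative to all mapped fragments. From the share of fragments in loci from 300 to under 1000 bp, a mean rise of 0.10 on the log2 scale was predicted for other loci in dek15, against 0.31 observed at loci of 1000 bp and over. The prediction was 0.20, 0.11 and -0.03 in dek15 replicates 1 to 3, against 0.35, 0.30 and 0.29 observed. It fell short of the observed rise in all 3 and had the opposite sign in replicate 3. The prediction leaves out abundant loci of 1000 bp and over, so its size and sign may depend on that length limit. It also rests on locus lengths with introns in place of transcript lengths, so it excludes nothing and the explanation stays open. Scaling on typical loci lowered the share to 60.4%, but such scaling centres the changes by construction and cannot tell a technical shift from a rise of most transcripts in dek15.

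The excess of calls on chromosome 4 from 160 to 190 Mb was weighed against 3 explanations. A change in copy number of the segment would move its loci together, yet their median log2 change differed from that of other loci by -0.010 (95% bootstrap interval -0.074 to 0.066). This argues against a shift of 0.2 or more of the segment as a whole, though not of a part of it. The bootstrap drew the segment's loci and not the libraries, so the interval leaves out the spread between samples. Expression level and spread were tested by shuffling the calls 10000 times among loci matched on both and searching each shuffle for its best run of 3 adjacent windows. This replaced draws of matched loci for the segment alone, which left out the search. The segment was the best of 180 runs, with an excess of 6.49 binomial standard deviations, against at most 5.42 in the shuffles (permutation p = 0.0001, the smallest they can give). The values were 6.34 and 5.78 with median of ratios scaling. This argues against level and spread as the whole cause, though shuffles treat neighbouring loci as independent. A linked haplotype carried with the mutation may contribute. The 22 loci that fell there do not test it, since these calls helped to choose the segment. Regional regulation would also give calls in both directions, and the 2 cannot be told apart without sequence variants.

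Deeper dek15 libraries were weighed as a source of the 18 loci listed at 0 in WT. The lowest dek15 value of each locus was divided by a low level that all WT libraries still list at loci of similar length (the 10th percentile of values above 0, within 10% of the length). Of the 6 loci of at least 1000 bp, 5 lay 13.3 to 300 times above that level. Depth alone is a poor account of these 5 if their transcripts are about as long as the loci, which include introns. The remaining locus lay 5.89 times above that level, short of the bound of 10. Deeper dek15 libraries are therefore not excluded for all loci of that length. Among the 12 loci under 1000 bp the ratio ran from 0.737 to 15.2, with 1 locus above 10, and depth stays open there. Failed estimates at short loci also stay open. Of the 18, 6 loci of at least 1000 bp remained, against at most 1 in any other split. These lengths include introns, so such a locus can carry a short transcript. Every other split mixes the groups, which holds its count down, so the comparison cannot exclude failed estimates. For all 18, other splits gave at most 5. A haplotype carried by the dek15 samples is a candidate explanation. Of the 18, 3 lay in the segment on chromosome 4, which is no test of it, since the segment was chosen for its calls. Switched-on transcription would give the same values, and the 2 cannot be told apart. Other causes were not tested, and values of whole kernels do not show which tissue the transcripts came from.

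Whether neighbouring loci respond together to the genotype stays open. Changes of adjacent loci within 50 kb correlated at 0.115 across 8640 pairs, above 8 of the 9 other splits and just below the highest, 0.118.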
